A study of Caenorhabditis elegans with 2 samples.

How the data were processed

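Chromatin immunoprecipitation followed by sequencing was done on whole L3 larvae of strain OP81, which carries an eGFP-tagged eor-1 transgene, in 2 biological replicates of 1 group. Per the labels, the libraries held fragments of 150 to 350 bp. The extraction protocol was not provided. The aligner, the peak caller, their versions and the threshold of the irreproducible discovery rate (IDR) are not given in the sources used here. Per the deposited README, candidate regions (peaks and background) were called with a control on each replicate and on the pooled alignments, and the optimal IDR list was then drawn from these lists, each in builds ce10 and ce11. Alignments, coverage tracks and the control itself were not used here.

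The deposited lists give for each region a signal value, on a scale that is not stated, and the −log10 of a q value. Each of the 3 candidate lists held 30000 regions in ce11, so their length carries no information on depth. Read depth is not given in the sources used here, so no precision can be attached to a single signal value. Because signal scales of different lists are not known to be comparable, the pooled value and the values of the replicates are given side by side without a mean. Shares are given with exact Clopper-Pearson 95% intervals, which cover counting error only.

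Lists in ce11 were used for all results, and lists in ce10 as an alternative, with no conversion between builds. Genes, transcripts and non-coding RNA genes were taken from Ensembl release 115. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. Tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Peaks on the mitochondrial genome were left out of the annotation, chromosome, sequence, gene and non-coding RNA tests.

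The agreement of the replicates was measured as the overlap, by 1 bp or more, of the 285 regions with the highest signal in each list. It was compared with 1000 random placements within chromosomes in a one-sided permutation test. Each summit was assigned to the first class that applied, with a promoter running from 1000 bp upstream to 200 bp downstream of a transcript start of a protein-coding gene. Classes were compared with 1000 random placements in two-sided permutation tests. Chromosome shares were compared with genome length in two-sided exact binomial tests. All 32896 words of 8 bases, with both strands merged, were counted within 50 bp of the summits and in windows centred 500 bp to each side. Words were tested on chromosomes I, III and V and counted again on the other chromosomes with two-sided Fisher's exact tests. A preset motif recalled for EOR-1 (GAGACGCAG or AGACGCAGA) and the shorter word GAGAG were counted in the same windows.

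A gene was called bound when a nuclear summit lay in its promoter window. The 29 gene lists were tested with two-sided Fisher's exact tests against protein-coding genes with a pooled candidate summit in that window. Summits within 200 bp of 5 classes of non-coding RNA gene, and candidate regions within 20000 bp of eor-1, unc-119 and eor-2, were compared with 1000 random placements or positions in one-sided permutation tests. P values were adjusted by the Benjamini-Hochberg method over the classes, chromosomes, words or lists tested together, with a threshold of 0.05.

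The genes named are eor-1, unc-119 and eor-2, those at the 25 promoter peaks with the highest signal, and up to 4 bound members of each list, with ties ordered by position. At the 25 peaks the bound gene with the closest transcript start was named, or both genes of a divergent pair. Bound microRNAs of the heterochronic list were to be named too. Other genes and regions are marked as chosen after their values were seen. The alternatives were other promoter, window and distance settings, the peaks of highest signal alone, each replicate left out in turn, other backgrounds, other overlap rules and ce10. The annotation, word and list tests were tested on simulated data: no promoter excess, word or list was called where nothing had been planted, and planted ones were called. The planted word was in 20% of 256 windows, but the real search used 117 windows. The planted list was tested among 19973 genes, but the real lists among 6412. The simulations therefore do not show the power of the real word search or of lists with few testable genes.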

Results

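Chromatin immunoprecipitation and sequencing mapped where EOR-1 sat on the genome of Caenorhabditis elegans L3 larvae. EOR-1 is a zinc finger transcription factor known to act downstream of Ras and Wnt signalling. The animals, of both sexes, carried an eGFP-tagged eor-1 transgene (wgIs81) and the unc-119(ed3) mutation. There was 1 group with 2 biological replicates and no second condition, so peaks were compared with the genome and between replicates. The optimal list held 285 peaks, of which 256 were nuclear and 29 were mitochondrial. Nuclear peaks had signal values from 52.7 to 384, with a median of 66.2. Read depth is not known. All positions are in build ce11, counted from 1, and signal values are those of the pooled list unless a replicate is named.

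The strongest promoter peaks lay at those of chaperone genes, of ftt-2 and of tos-1. The highest nuclear signal, 384, was at V:9344223–9344436, with its summit 130 bp upstream of tos-1, and was 163 in replicate 1 and 219.9 in replicate 2. The next promoter peak, III:8447080–8447247, had a signal of 279 (159 and 120.4 in replicates 1 and 2). It lay between hsp-110, an Hsp110-family chaperone gene, and rpn-3, which encodes a proteasome regulatory subunit. The peak IV:17278440–17278644 upstream of hsp-1, the constitutive Hsp70 gene, had 266 (128 and 139). The peak X:11605694–11605944 upstream of ftt-2, a 14-3-3 gene, had 232 (116 and 123).

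Other promoter peaks of high signal lay at dnj-13, which encodes a J-domain co-chaperone, and F54D5.9 (189), and at hsp-90, the cytosolic Hsp90 gene, and C47E8.4 (169). The histone gene his-37 had 193, the nematode-specific gene nspc-17 had 210.1, H41C03.3 had 191, the insulin-like gene ins-39 had 169 and Y39E4B.6 had 155. Peaks with signals of 127 to 143 lay at ntl-11, a CCR4-NOT subunit gene, at the cell corpse engulfment gene ced-5 with F01D4.5, at the RNA-binding protein gene fust-1, and between icd-1 and vps-32.1. Signals of 103.96 to 126 were found at scpr-1 and gpap-1, ekl-4 and rps-20, dpm-3 and rps-23, ufbp-1, egg-5, ints-4, tent-5, sac-2 and rpl-31, and cyn-10. These 25 promoter peaks, of which 2 were at ftt-2, were named by rank, and all had the highest −log10 q value in the list, 2.50. That value was shared by 160 peaks, so it does not order them.

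The replicates shared many of their strongest regions. Of the 285 regions with the highest signal in replicate 1, 147 overlapped one of the 285 of replicate 2 (51.6%, 95% interval 45.6–57.5). Random placement gave a mean of 25.97 (one-sided permutation p = 0.001, the smallest that 1000 placements can give). The peaks at tos-1, hsp-110 and hsp-1 ranked 26, 27 and 31 in replicate 1 and 26, 35 and 31 in replicate 2, and in the pooled list the first 25 peaks were mitochondrial. Some other peaks were less even: the peak at daf-14 (59.9) had 40.8 in replicate 2 but 13.5, at rank 10677, in replicate 1. The peak at pbrm-1 (70.2) overlapped no candidate region of replicate 1. The same held for stronger peaks, among them IV:2219524–2219819 (113) and that at set-16 and drr-2 (103), named after their values were seen. Of the 285 optimal peaks, 201 were among the top regions of replicate 1, 205 among those of replicate 2, and 26 in neither. In the first 1425 regions of each replicate the overlap was 26.2%.

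Across the 277 optimal peaks found in both candidate lists, the signals of the replicates had a Spearman rho of 0.59 (bootstrap 95% interval 0.47–0.68) and a Pearson r of 0.93 on the log2 scale. Peaks are not independent replicates, so no p value is attached. The optimal list was drawn by IDR from these same replicates, and only peaks in both lists entered. The correlations therefore describe the selected peaks and are no separate measure of agreement. In nuclear regions alone, a split chosen after the data were seen, 120 of 258 top regions overlapped (46.5%), against 0.417 by chance (one-sided permutation p = 0.001, the smallest possible). Across the 249 nuclear peaks found in both lists, the Pearson r was 0.63.

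**Figure D1:**
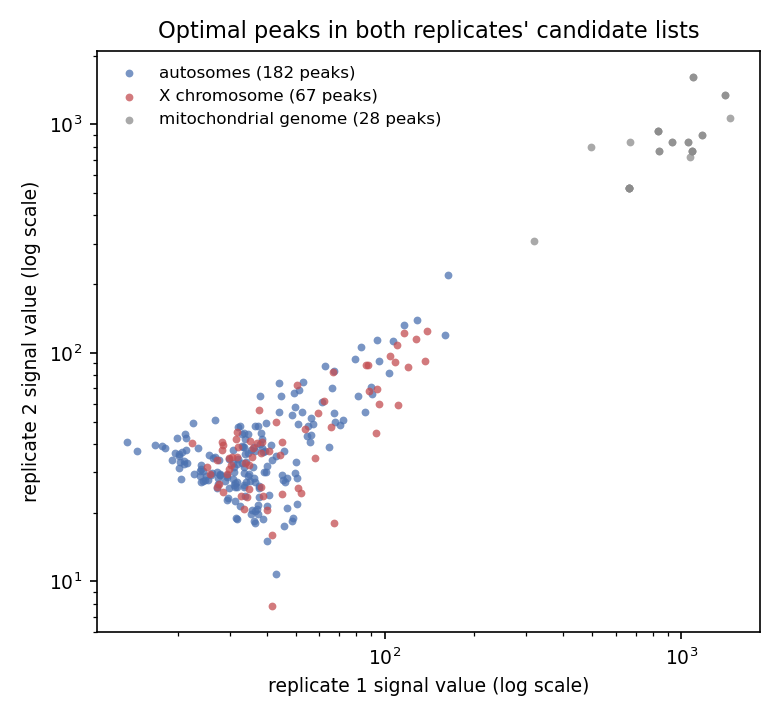
Signal value in replicate 2 against replicate 1, both on log axes, for the optimal peaks found in both candidate lists, with peaks on autosomes, the X and the mitochondrial genome in different colours. Mitochondrial peaks lie at the top of both axes, and nuclear peaks have a Spearman rho of 0.43.

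EOR-1 peaks lay in promoters more often than random placement gives, and not in coding exons outside promoter windows. Of the 256 nuclear summits, 143 fell in a promoter (55.9%, 49.5–62.04), against 25.4% of random placements. None was assigned to a coding exon (0 of 256, which allows up to 1.43%), against 18.7% at random. Among candidate regions outside the optimal list, matched on chromosome, 1.82% were (adjusted two-sided permutation p = 0.0233 against these). Coding sequence inside a promoter window counted as promoter, so summits there are not excluded. Introns held 36 (14.1%), against 27.7% at random. Against random placement, all 3 classes had an adjusted two-sided permutation p = 0.0047 over 7 classes, from the smallest unadjusted p that 1000 placements can give. The 4 summits in 3′ UTRs, named after their values were seen, were in prx-10, mxl-3, C05D11.8 and F45D3.3 (1.56%, against 2.38% at random).

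The promoter peaks had their median summit 203 bp upstream of the transcript start. At 51 of 143 (35.7%), including those of hsp-110 and rpn-3, ced-5 and F01D4.5, and ekl-4 and rps-20, the summit lay between divergent genes. In all, 196 protein-coding genes were bound. Non-coding genes held 11 summits (4.30%, against 3.14%; adjusted permutation p = 0.647) and intergenic sequence 62 (24.2%, against 22.3%; adjusted permutation p = 0.664). Against candidate regions outside the optimal list, matched on chromosome, the intergenic share was instead lower (24.2% against 30.2%; adjusted two-sided permutation p = 0.0336) and the excess in non-coding genes passed the threshold (adjusted permutation p = 0.0245). Several of the 11 summits in non-coding genes lay close together, at X:16929922–16931764. The test draws summits independently, so this excess may rest in part on that stretch.

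**Figure D2:**
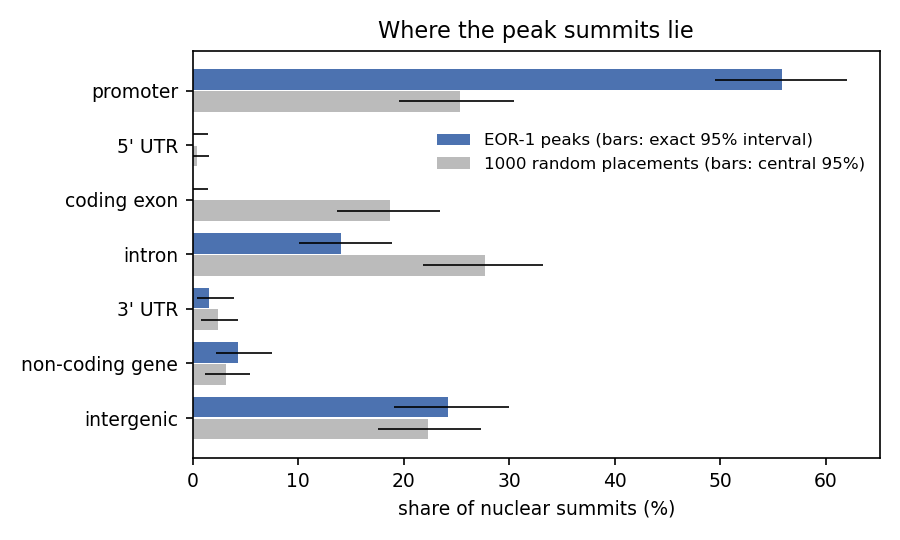
Share of nuclear peak summits, in percent, in each class of sequence for EOR-1 peaks and for 1000 random placements, with exact 95% intervals and the central 95% of placements as bars. Promoters held 55.9% of summits against 25.4% at random, and coding exons outside promoter windows none.

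The X chromosome held more peaks than its length predicts, and chromosome V fewer. On the X lay 67 of 256 nuclear peaks (26.2%, 20.9–32.0), against 17.7% of the genome (1.48-fold, exact binomial adjusted p = 0.0044 over 6 chromosomes, two-sided). Chromosome V held 34 (13.3%, 9.38–18.1), against 20.9% (adjusted exact binomial p = 0.0061, two-sided). X peaks were common at the top of the list, with 14 of the first 25 nuclear peaks. Among the strongest outside promoters, named after their values were seen, were X:2996960–2997255 in an intron of Y41G9A.17 (262), X:8036355–8036501, 4870 bp upstream of the sex determination gene xol-1 (243), and X:11094020–11094287 near W02H3.3 (227).

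Measured against the share of pooled candidate regions on each chromosome, neither difference passed the threshold: 21.4% of candidates were on the X and 17.2% on V (adjusted exact binomial p = 0.196 for both). Split by position, also after the data were seen, 47 of the 113 peaks outside promoters were on the X (41.6%, 32.4–51.2), but 20 of the 143 in promoters (13.99%; two-sided Fisher's exact p = 7.9e-07, odds ratio 4.38). Some X peaks outside promoters lay close together, as at X:16929212–16931911 and in introns nearest to unk-1. The tests of chromosome shares counted each peak as independent, so their p values may be too small.

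**Figure D3:**
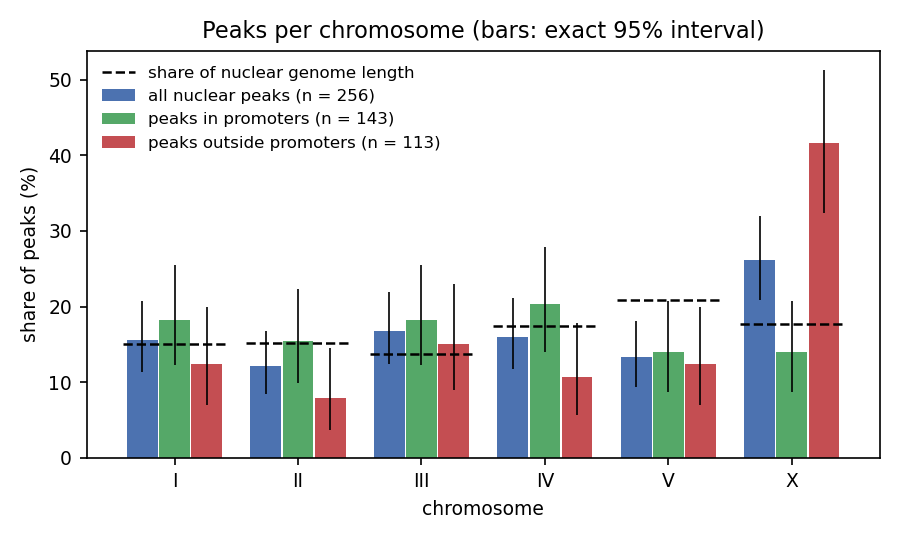
Share of peaks, in percent, on each chromosome for all 256 nuclear peaks, the 143 in promoters and the 113 outside them, with exact 95% intervals as error bars and the share of nuclear genome length as dashed lines. The X holds 26.2% of all peaks and 41.6% of those outside promoters, against 17.7% of the genome.

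The summits carried the motif recalled for EOR-1 more often than flanking sequence. GAGACGCAG or AGACGCAGA lay within 50 bp of 30 of 256 summits (11.7%, 8.05–16.3), against 4 of 512 flanking windows (0.781%; two-sided Fisher's exact p = 1.7e-11, odds ratio 16.9). Peaks with the motif included those at ntl-11, fust-1 and tent-5, and, named after their values were seen, an intron peak nearest to epg-9 (222) and the promoter peak shared by hsp-16.2 and hsp-16.41 (103). That was 1 of the 8 peaks of the heat shock list, against 19 of 135 other promoter peaks (two-sided Fisher's exact p = 1), and the peaks at hsp-110, hsp-1, dnj-13 and hsp-90 lacked the motif. The shorter word GAGAG lay at 84 summits (32.8%, 27.1–38.9), against 85 flanking windows (16.6%; two-sided Fisher's exact p = 7.7e-07). By rank of nuclear signal, it was found at 8 of the first 25 peaks, 13 of those ranked 26 to 50, 27 of those ranked 51 to 100, 16 of those ranked 101 to 150, 10 of those ranked 151 to 200 and 10 of the 56 ranked 201 to 256. In the same order of ranks, the preset motif was at 2, 7, 7, 4, 6 and 4 peaks, so most of the first 25 lacked it.

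In the search over all 32896 words, none passed the threshold after adjustment, and 195 had an unadjusted Fisher's exact p under 0.05. The first word, AGACGCAG, which is the part shared by both forms of the preset motif, was at 15 of 117 summits on chromosomes I, III and V and in 3 of 234 flanking windows (two-sided Fisher's exact p = 1.1e-05, adjusted p = 0.121). On the other chromosomes it was at 16 of 139 summits (11.5%) and in 1 of 278 flanking windows (0.36%; two-sided Fisher's exact p = 1.5e-07). GACGCAGA and GAGACGCA tied with it in the first test.

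Heat shock protein genes had an excess of bound promoters. Of 27 tested genes of the hsp, hsf and dnj families, 9 were bound (33.3%, 16.5–53.96), against 2.93% of other genes (two-sided Fisher's exact p = 5.6e-08, adjusted p = 1.6e-06 over 29 lists). They included hsp-110 (279), hsp-1 (266), dnj-13 (189) and hsp-90 (169). The other 5, named after their values were seen, were hsp-16.2 and hsp-16.41, which share a peak (103), hsp-60 (68.9), dnj-12 (60.5) and dnj-9 (52.8). Among all 50 genes of these families, with or without a candidate region, the bound share was 18% (adjusted Fisher's exact p = 3.6e-08). When each peak counted only for its closest gene, 5 of 27 were bound (18.5%, adjusted Fisher's exact p = 0.0036). That alternative was chosen after the data were seen. At hsp-90 the closer transcript start was that of C47E8.4 (258 bp against 417 bp). At hsp-60 it was that of Y22D7AL.10, named after its values were seen (181 bp against 632 bp). The peak between hsp-110 and rpn-3 had its summit at 8447154, which is 245 bp upstream of hsp-110 and 199 bp upstream of rpn-3.

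**Figure D4:**
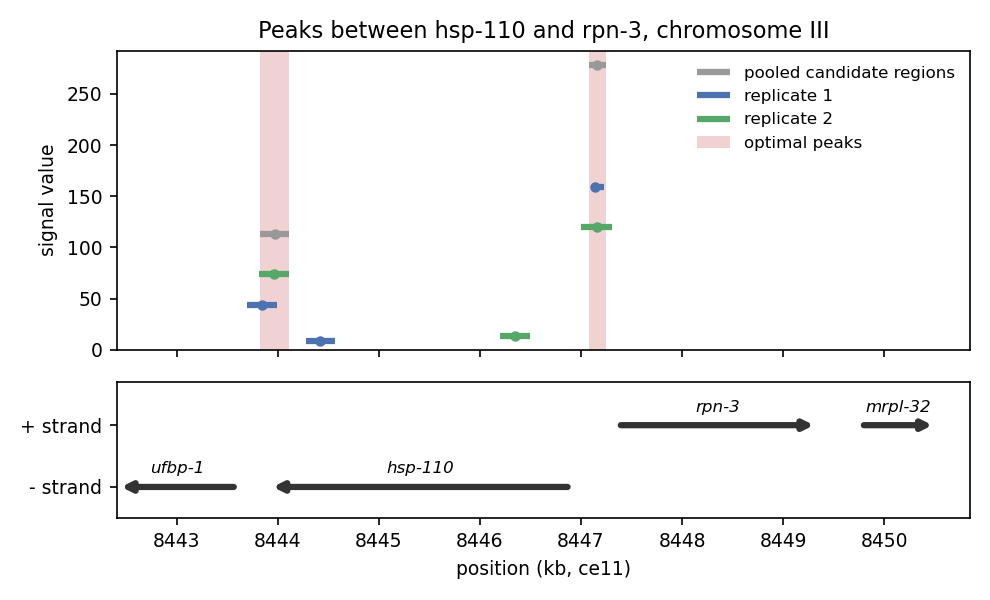
Signal value of candidate regions of the pooled list and of each replicate along chromosome III (kb, build ce11), with optimal peaks shaded and genes drawn below as arrows in the direction of transcription. The peak between hsp-110 and rpn-3 reaches 279 in the pooled list, 159 in replicate 1 and 120.4 in replicate 2.

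Cytosolic ribosomal protein genes were bound at 7 of 33 (21.2%, 8.98–38.9), against 2.96% of other genes (two-sided Fisher's exact adjusted p = 0.000471). Their strongest peaks were at rps-20 (117), rps-23 (114.6), rpl-31 (104.4) and rps-26 (80.03). At each of these 4 a neighbour, ekl-4, dpm-3, sac-2 and tmem-107 in turn, had the closer transcript start. When each peak counted only for its closest gene, 2 of 33 were bound (6.06%, adjusted Fisher's exact p = 0.424) and the call was lost. Among all 81 ribosomal protein genes the share was 8.64% (adjusted Fisher's exact p = 0.00014). Chemoreceptor genes, the control list, were bound at 0 of 389 (which allows up to 0.944%), against 3.25% of other genes (two-sided Fisher's exact adjusted p = 0.00014). Among the peaks of highest signal alone, that depletion had an adjusted Fisher's exact p = 0.0613.

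Other lists did not pass the threshold. Bound were 2 of 8 histone genes (his-37, 193, and his-71, 57.0; adjusted Fisher's exact p = 0.134), 2 of 6 proteasome genes (rpn-3, and pbs-2, 55.4; adjusted Fisher's exact p = 0.0932) and 2 of 13 respiratory chain genes (cox-6A, 73.1, and cox-5A, 55.3; adjusted Fisher's exact p = 0.241). In replicate 2's own top regions, 42.9% of the proteasome list (adjusted Fisher's exact p = 0.0055) and 20% of the respiratory chain list (adjusted Fisher's exact p = 0.0479) were bound, both past the threshold. In replicate 1's own top regions, 16.7% of the proteasome list (adjusted Fisher's exact p = 0.648) and 0 of 13 genes of the respiratory chain list (adjusted Fisher's exact p = 1) were bound.

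In the Ras-ERK list, the pathway with which EOR-1 is known to act, 1 of 13 genes was bound: egl-17, an FGF gene (88.0; adjusted Fisher's exact p = 0.602). Its summit was also within 200 bp of a tRNA gene, as was that at ajm-1. A further 9 lists each had 1 bound gene: daf-14 for TGF-beta (59.9), akt-2 for insulin (68.8), lin-28 for the heterochronic pathway (53.7), pbrm-1 for SWI/SNF (70.2), ced-5 for cell death (135), mup-2 for muscle (60.8), ajm-1 for epidermis (63.0), wve-1 for small GTPases and cytoskeleton (60.3) and ins-39 for neuropeptides (169). Adjusted two-sided Fisher's exact p values in these 9 lists were 0.463 or more.

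No bound gene was found among 121 nuclear hormone receptor genes (which allows up to 3.00%; adjusted Fisher's exact p = 0.241), 27 cuticle collagen genes (up to 12.8%), 21 ceh homeobox genes (up to 16.1%), 20 C-type lectin genes (up to 16.8%) or 15 neuron markers (up to 21.8%; adjusted Fisher's exact p = 1 for the last 4 lists). The Wnt, Notch, Hox, cell cycle, intestine, pharynx, germline and junction lists had none bound either (adjusted Fisher's exact p = 1 for each). Each of these had under 10 testable genes. At these sizes, and in the collagen, ceh, lectin and neuron lists too, a share below the 3.06% of all background genes was not detectable.

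**Figure D5:**
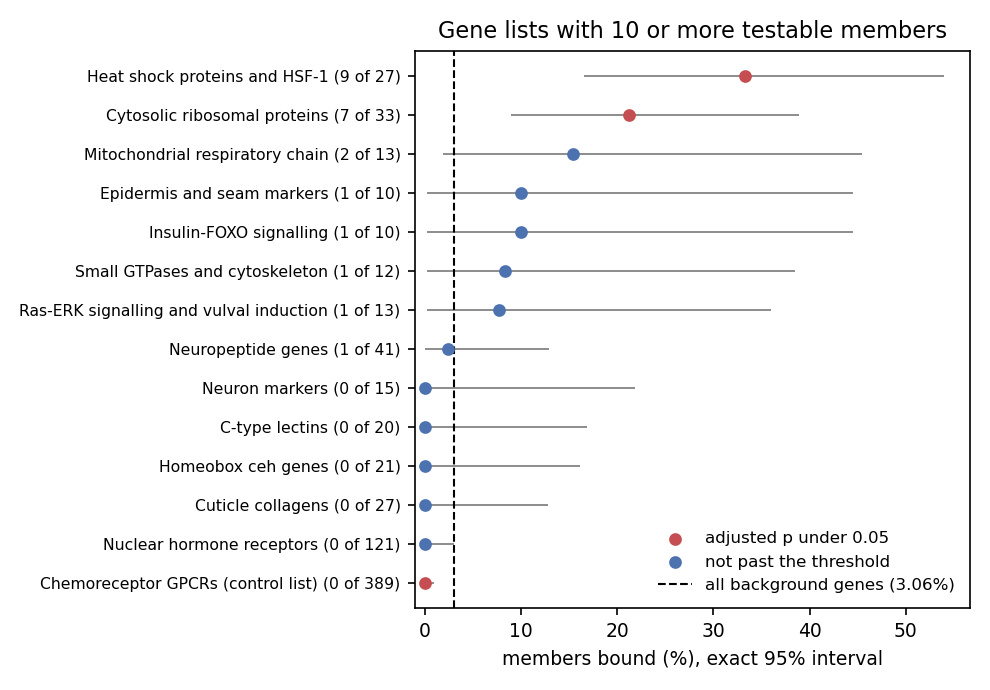
Share of testable genes with an EOR-1 peak in the promoter, in percent with exact 95% intervals, for each list with 10 or more testable genes, with the share of all background genes as a dashed line. Heat shock proteins (33.3%) and cytosolic ribosomal proteins (21.2%) lie above the line of 3.06%, and chemoreceptors (0 of 389) below it.

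Peaks lay near tRNA, small nuclear RNA and small nucleolar RNA genes more often than chance gives. A tRNA gene was within 200 bp of 14 of 256 summits (5.47%, 3.02–9.01), against a mean of 0.808 at random, and a small nuclear RNA gene within 200 bp of 5 (1.95%, 0.637–4.50), against 0.151. Each had an adjusted one-sided permutation p = 0.0025 over 5 classes, from the smallest unadjusted p possible. The 5 small nuclear RNA genes, named after their values were seen, were the spliced leader genes sls-2.1 (191), sls-2.4 (113), sls-2.2 (108) and sls-2.8 (75.9), and F54D8.7 (73.1). Most of these peaks also lay in promoters of protein-coding genes: that at sls-2.1 is the one of H41C03.3, that at sls-2.4 of egg-5, that at sls-2.8 of tim-1 and Y75B8A.23, and that at F54D8.7 of cox-6A. Among small nucleolar RNA genes, the peak at F39B2.14 is the one of rps-26 and tmem-107, that at T02E1.9 of T02E1.2 and that at Y53F4B.47 of cmtr-1. The 4 small nucleolar RNA genes, also named afterwards, were T02E1.9 (80.5), F39B2.14 (80.03), ZK994.7 (56.1) and Y53F4B.47 (55.5), against 0.414 at random (adjusted one-sided permutation p = 0.0050).

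No summit was near a ribosomal RNA or microRNA gene (0 of 256, which allows up to 1.43%; one-sided permutation p = 1 for both). Of the heterochronic microRNAs, let-7 was not matched in the annotation and has no value, lin-4 was 57427 bp from the nearest summit, mir-84 34094 bp, mir-48 164338 bp and mir-241 166112 bp.

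The genes of the transgene and of the EOR-1 partner EOR-2 had no optimal peak. Within 20000 bp of eor-1 (IV:4793194–4799178) there were 0 candidate regions in the pooled list, against a median of 12 at random autosomal positions, 56 of 1000 of which had as few (lower-tail permutation p = 0.0569, one-sided, a test chosen after the count was seen, since the planned test for an excess gave p = 1). Replicate 1 had 0 candidates there (lower-tail permutation p = 0.025) and replicate 2 had 2 (p = 0.0829). In the pooled list the lower-tail permutation p was 0.265 within 5000 bp of eor-1 (0 candidates against a median of 4). It was 0.212 within 50000 bp (17 against 29). Near unc-119 (III:10902641–10908935), the gene mutated in the strain, there were 25 candidates against a median of 12 (one-sided permutation p = 0.128), with a highest signal of 32.8 against 32.6 (one-sided permutation p = 0.493). Near eor-2 (X:14603017–14608660) there were 8 candidates, against a median of 12 (one-sided permutation p = 0.678). Their highest signal was 23.2, against 32.4 (one-sided permutation p = 0.806). The random positions were autosomal, but eor-2 is on the X, where candidates were more frequent. They are therefore not a matched reference for eor-2.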

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

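No test in this part was chosen after its result was seen. A closer look was prompted by signal in data that the comparisons of the nuclear genome do not use: 29 of the 285 optimal peaks were on the mitochondrial genome. Their median signal was 1223, against 66.2 for nuclear peaks, and the first 25 peaks of the optimal list were all mitochondrial. The 29 peaks merged into 13 regions. Pooled candidate regions covered 87.7% of the 13794 bp mitochondrial genome, above the 80% named in advance for reads spread over a genome present in many copies, so that spread is a candidate explanation. The values of the control are not used here, and no biological explanation was tested, since the design has 1 group.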

How the results depend on the processing

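Nuclear-only regions and closest-gene counting were chosen after seeing the data. In all, 57 results were recomputed under 367 alternatives. Among the main results 58 alternatives were counted as the same, and among single classes, chromosomes and lists 297 were. For called results this means that direction and call were kept. A result without a call counted as the same whenever the alternative had no call either, whatever its direction. Counts and correlations were judged by how near their values stayed. The overlap of the replicates ran from 26.2% to 66.2%, the promoter share from 46.1% to 64.8%, the motif share from 9.30% to 14.8%, and the heat shock share from 18% to 38.1%, all past the threshold.

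Taking only the peaks of highest signal gave 142 peaks and 91 bound genes, by construction. In nuclear peaks rho moved to 0.43, because mitochondrial peaks were left out. The X share of 26.2% no longer passed against the share of candidate regions (adjusted exact binomial p = 0.196, with 9.0e-06 to 0.196 over its alternatives), because candidates are themselves more frequent on the X. Without a replicate, 3 to 5 lists passed, against 3; the 5 were without replicate 1, and the cause was not tested. The intergenic share of 24.2% reversed, to lower than the background, against candidate regions (adjusted permutation p = 0.0336), since 30.2% of those were intergenic. A further 3 results lost their call and 3 gained one. Left without a replicate, 137 and 132 of the 196 bound genes were shared. No paired analysis was possible because there was 1 group only. Read depth is not known, so its effect on the weaker peaks could not be measured.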

Other observations

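Chosen only after the results were seen were the tests of tRNA genes on the X, of spliced leader genes, of motif shares by chromosome and of the candidate gap at eor-1, and, among the explanations weighed, those against housekeeping lists and of candidates outside promoters. Peaks at tRNA genes were almost all on the X: 13 of 67 X peaks were within 200 bp of a tRNA gene (19.4%), against 1 of 189 autosomal peaks (two-sided Fisher's exact p = 1.2e-07). Counted by gene, 15 of 276 tRNA genes on the X and 1 of 336 on autosomes had a summit nearby (two-sided Fisher's exact p = 4.9e-05). Pooled candidate summits near tRNA genes were also more frequent on the X, with 114 of 6423 (1.77%) against 49 of 23547 on autosomes (0.208%; two-sided Fisher's exact p = 3.2e-40). The strongest of these optimal peaks was X:5801169–5801464 (signal 114), between a pair of tRNA genes. Of the 18 genes of the SL2 spliced leader RNA, which is added to downstream genes of operons, 4 had a peak (22.2%, 6.41–47.6), against 1 of 111 other small nuclear RNA genes (two-sided Fisher's exact p = 0.0013).

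The eor-1 gene lay in a stretch of 97002 bp without a pooled candidate summit (IV:4733733–4830735), and 23 of 29964 gaps between neighbouring summits were as long, itself included. In replicate 1 the stretch was 84962 bp, with 21 of 29967 gaps as long. In replicate 2 it was 49781 bp, with 103 of 29965 as long. A longer gap covers more positions, so these counts do not give the chance that a gene lies in such a gap. Against random autosomal positions, the lower-tail permutation p for pooled candidates near eor-1 was 0.0569 within 20000 bp and 0.212 within 50000 bp.

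Peaks at heat shock promoters were weighed against 3 explanations. Longer upstream regions are argued against, since within bins of upstream length the list kept an adjusted permutation p = 0.0029. Binding at housekeeping promoters in general stays open: 9 of 27 heat shock genes and 11 of 52 ribosomal, proteasome and respiratory chain genes were bound (33.3% and 21.2%, two-sided Fisher's exact p = 0.281). The peak between hsp-110 and rpn-3 counts on both sides, and hsp-16.2 and hsp-16.41 share a peak, so these counts are not independent. Heat shock elements, the sites of HSF-1, were at 2 of 8 peaks of the list, at hsp-110 with rpn-3 and at hsp-16.2 with hsp-16.41. They were at 3 of 135 other promoter peaks (two-sided Fisher's exact p = 0.0253). Over all nuclear summits they were at 9 of 256, against 4 of 512 flanking windows (Fisher's exact p = 0.0132). Bound and unbound promoters of the list were not compared, so the excess at list peaks may go with the genes rather than with binding. A shared site therefore stays open. The design has 1 group, so no comparison between groups tests this or another biological explanation.

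The excess of X peaks was weighed in the same way. A single replicate is argued against, since 2 of 2 replicates had an X share above the genome share (27.5% and 30.1%, exact binomial tests). A higher share of candidate regions on the X may account for the excess over all peaks (two-sided exact binomial p = 0.0676), but not for that outside promoters (41.6% against 22.7% of candidates, exact binomial p = 8.2e-06). These tests counted X peaks that lie close together as independent. The word GCGCAGGG, known from recruitment sites of the dosage compensation complex, was at 11 of 67 X summits, including those near xol-1 and W02H3.3. It was at 0 of 189 autosomal summits (two-sided Fisher's exact p = 2.1e-07). This test used no X sequence away from the summits, so it cannot tell a word of the X peaks from one frequent on the X. Such sites are a candidate explanation for some of the X peaks, one that no comparison between groups could test here. GCGCAGGG was at 8 of 47 X peaks outside promoters (17.02%) and 3 of 20 in promoters (15%). Among the first 50 nuclear peaks it was at 9 of the 20 X peaks (45%). These differences were not tested.

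The preset EOR-1 motif was at 2 of 67 X summits, those nearest to gtr-1 and epn-1 (2.99%), and at 28 of 189 autosomal summits (14.8%; two-sided Fisher's exact p = 0.0076).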
